A study of Mus musculus with 47 samples.

How the data were processed

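The samples were proximal colons of male mice of 10 weeks from the lines A/D and B6D, each labelled KO or WT for Ptges, 47 libraries in all. Per the labels' protocols, tissue was homogenised, RNA was extracted with RNeasy Midi kits and assessed on a Bioanalyzer, and libraries were made with the TruSeq Standard mRNA kit; the mice had no treatment. The authors deposited raw counts of reads per gene for 55487 Ensembl genes, whole numbers that were not normalised. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and counted with featureCounts of Subread 2.0.3 on GRCm38 (mm10). The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping and antisense genes therefore cannot be told apart, and counts of near-identical copies are uncertain.

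Groups were taken from the sample labels, and each column of the count table was matched to its sample by name. No column was left out, and no 2 columns were identical. Gene symbols were found for 55141 of the 55487 identifiers and coordinates for 55227, in a mouse annotation of GRCm38. Totals ran from 4690000 to 8715401 counts per library, with group medians of 6117788 (A/D KO), 6376988 (A/D WT), 6393276 (B6D KO) and 6362197 (B6D WT). Where a group had no count of a gene, a floor of 3 counts over the group was used, worth 0.0363 to 0.0415 CPM. Such bounds cover counting error only.

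Counts were analysed with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust quasi-likelihood fits, Benjamini-Hochberg adjustment, threshold 0.05) in a model of 4 group means over all 47 libraries with 43 residual degrees of freedom. The filter left 14628 genes. The comparisons were KO against WT in each line, the difference of these effects, and A/D against B6D within each label. A gene that passed the threshold is said to be called, to have risen or fallen, or to be higher or lower. Each SE of a log2 fold change came from the fit. Levels are CPM with TMM library sizes. Lists of genes (45 lists, 21 of pathways and 24 of cell types, 43 of them with at least 3 tested members) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation. The list symbols Ctgf and Si were read as Ccn2 and Sis (sucrase-isomaltase). Overlaps and the neighbourhood of Ptges were tested with Fisher's exact test. The comparisons, the lists, the threshold, the rule for named genes and most of the other settings below were fixed before the data were examined.

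The rule named, for each comparison, Ptges; the 8 largest increases and 8 largest decreases among called genes; the 3 smallest p-values among these eligible genes; and up to 4 called members of each list, of which the text gives a few. Eligible genes had a mean of at least 1 CPM in the higher group and an established symbol. They were not variable, diversity or joining segments of immune receptors, while constant genes could be named. Except for the difference of effects, at least 75% of the libraries of the higher group lay above the median of the lower group and at least 75% of the lower group below the median of the higher. A gene named in 1 comparison could be given in others. Gal3st2, Cyp4b1 and Carmn, named by the rule in A/D, are not described because their calls ended without 1 library in several fits.

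Other settings fixed beforehand were DESeq2 1.42.0 size factors, DESeq2's own test, limma voom with quality weights, no filter, a stricter filter (CPM of at least 1 in at least 11 libraries), the replicate number as a block, the smooth muscle score as a covariate, only the groups compared, leaving out each library, other windows around Ptges and other thresholds. After the data were seen, fits with a length score as covariate and without 7 libraries were added. The length score of a library is the mean log2 CPM of protein-coding genes whose longest transcript has at most 2250.5 bases minus that of genes with at least 4870.5 bases (6698 genes), centred over libraries. The 7 libraries are those above 0.5 (A/D KO 4 and B6D WT 2, 3, 5, 10, 12 and 13). Scores were compared between groups with permutation tests of 100000 resamples.

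The fit was tested on simulated data over 14628 genes. In the A/D comparison, 73.1%, 92.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, 4 of 189 calls were of unchanged genes, and 0 genes were called when none was changed. The simulated counts were drawn independently for each gene, without a length trend or differences in tissue makeup between libraries. The simulation therefore does not show the rate of false calls in the real libraries. A fit without the A/D KO libraries of highest Il1b was tried and is not reported, because it picks libraries by an outcome.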

Results

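Gene expression was measured by bulk RNA sequencing in the proximal colon of male mice of 10 weeks from 2 lines, A/D and B6D, whose names the labels do not expand. Within each line, libraries were labelled KO or WT for Ptges, the gene of microsomal prostaglandin E synthase, which makes prostaglandin E2. There were 12 A/D KO, 12 A/D WT, 11 B6D KO and 12 B6D WT libraries. The stated purpose was to look for genes that may go with the different liability of these lines to colonic ulcers. Total counts per library ran from 4690000 to 8715401, with a median of 6289620. The lines were housed apart, so line and housing cannot be told apart in any comparison between them. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples.

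Ptges, the targeted gene (ENSMUSG00000050737, chromosome 2, 30889471 to 30929863, GRCm38), was higher in the libraries labelled KO than in those labelled WT in both lines. In A/D its level was 32.9 ± 7.52 CPM (counts scaled to a common library size, mean ± SD, n = 12) in libraries labelled KO and 7.10 ± 1.03 (n = 12) in libraries labelled WT. In B6D the levels were 29.1 ± 3.66 (n = 11) and 6.13 ± 1.37 (n = 12). The log2 fold change was 2.21 ± 0.11 (SE) in A/D and 2.25 ± 0.12 in B6D. The adjusted p-values were 5.7e-21 and 1.4e-20 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for all adjusted p-values of single genes). The difference between the lines' fold changes was -0.04 ± 0.16 (adjusted p = 0.86). The lowest library labelled KO exceeded the highest labelled WT of its line by a factor of 2.10 in A/D and 2.98 in B6D. Ptges thus went against the labels in every library, and counts per gene do not show which exons the reads came from. All directions below follow the labels as deposited.

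**Figure D1:**
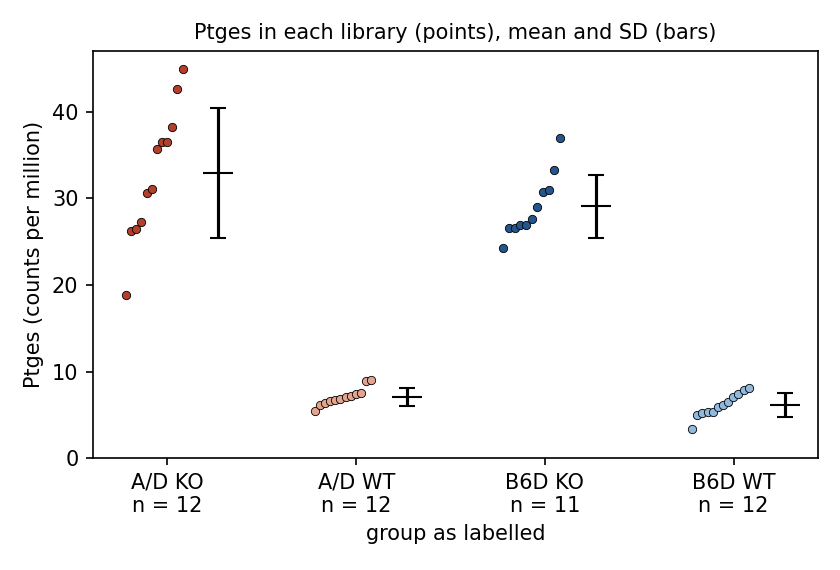
Ptges in CPM (vertical axis) for each library (points, sorted by value within a group), by group as labelled (horizontal axis); the bar beside each group is the mean with its SD. Libraries labelled KO sit between 18.9 and 44.9 in A/D and between 24.3 and 37.0 in B6D, all above the libraries labelled WT of their line.

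The libraries also differed in tissue makeup and in the balance of short and long transcripts. A smooth muscle score, the mean log2 level of 15 smooth muscle genes centred over all libraries, was -0.41 ± 0.37 (mean ± SD) in A/D KO and 0.06 ± 0.12 in A/D WT. It was 0.01 ± 0.15 in B6D KO and 0.35 ± 0.16 in B6D WT. A length score, the mean log2 level of genes with short transcripts minus that of genes with long ones, was 0.00 ± 0.29, -0.25 ± 0.18, -0.21 ± 0.15 and 0.44 ± 0.43 in the same order. Between libraries labelled KO and WT, the smooth muscle score differed by -0.47 in A/D and -0.34 in B6D (permutation tests, two-sided, p = 2e-04 and 2e-05, BH-adjusted over 8 tests 0.00032 and 0.00011). The length score differed by 0.25 and -0.64 (p = 0.019 and 0.00019, BH-adjusted 0.022 and 0.00032). Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation with transcript length of -0.44 in A/D and 0.65 in B6D. With the length score as a covariate, a fit chosen after the data were seen, these correlations were 0.04 and 0.02. The score is built from genes with short and long transcripts in these same libraries, so the correlations were bound to shrink. Values from that fit are called length-adjusted below.

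**Figure D2:**
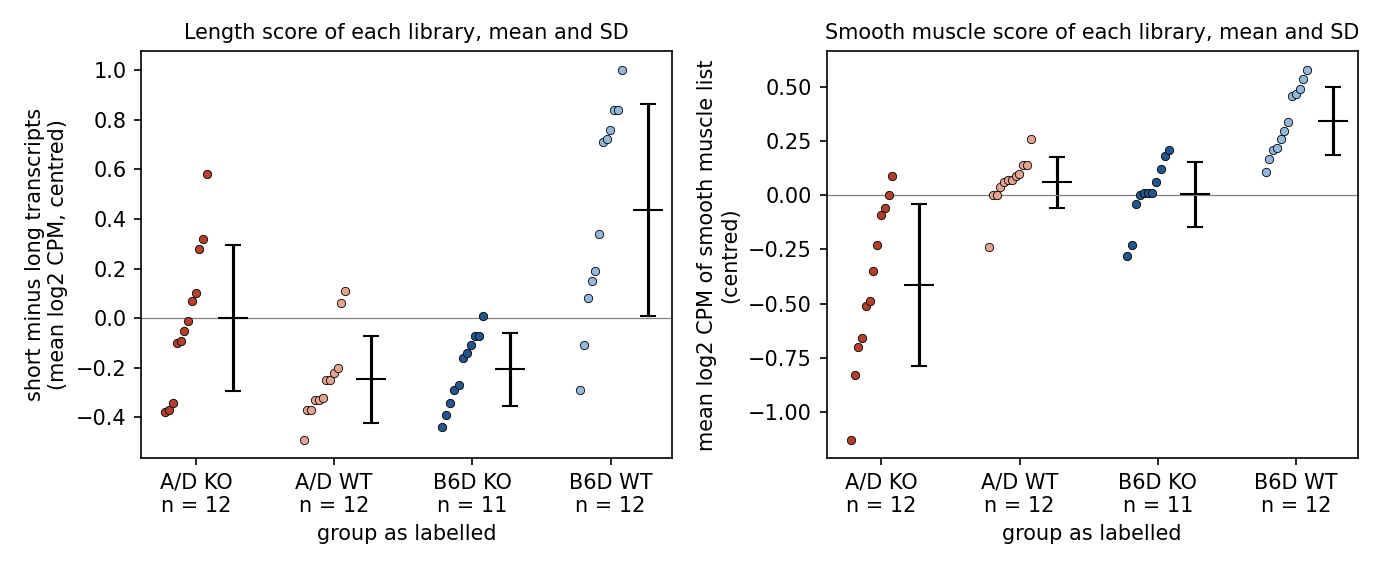
Length score (left) and smooth muscle score (right), both in log2 CPM centred over the 47 libraries (vertical axes), for each library (points, sorted within a group) by group as labelled (horizontal axes); bars are means with SD. Length scores are highest in B6D WT, with a mean of 0.44, and smooth muscle scores lowest in A/D KO, with a mean of -0.41.

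In the A/D line, genes of inflammation and tissue injury were higher in libraries labelled KO than in those labelled WT. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, rose by a log2 fold change of 4.09 ± 0.67 (SE; adjusted p = 3e-04), from 1.17 ± 0.576 to 19.9 ± 33.4 CPM (mean ± SD, n = 12 and 12). Hp, the acute-phase protein haptoglobin, rose by 4.16 ± 0.76 (adjusted p = 0.00098). The matrix-degrading enzymes Mmp3 and Mmp10 rose by 3.66 ± 0.60 and 3.49 ± 0.58 (adjusted p = 0.00027 and 3e-04). Slpi, a secreted inhibitor of leukocyte proteases, rose by 3.23 ± 0.50 (adjusted p = 0.00013) and Clca4b, of the calcium-activated chloride channel regulators, by 2.97 ± 0.41 (adjusted p = 1.5e-05). The immunoglobulin heavy chain genes Ighg2c and Ighg2b rose by 2.64 ± 0.58 and 2.56 ± 0.42 (adjusted p = 0.0058 and 3e-04). The rise was uneven between libraries. For Il1b and Hp, 6 of the 12 libraries labelled KO lay above the highest A/D library labelled WT, and for Mmp3, Lcn2 and Slpi 7 of 12. Il1b ran from 0.57 to 104 CPM among libraries labelled KO, with a median of 2.88 against 1.05 in A/D WT. Without A/D KO library 9, the log2 fold change was 3.39 for Il1b, 2.42 for Slpi and 1.66 for Ighg2c, whose call then ended (adjusted p = 0.053). With the smooth muscle score as a covariate, Clca4b (2.68) and Ighg2b (2.49) were still called and the other 6 genes given by fold change here were not. Their folds stayed positive but were smaller, with Hp at 3.29 ± 0.90, Il1b at 2.27 ± 0.77, Mmp3 at 2.15 ± 0.72, Mmp10 at 2.04 ± 0.71, Slpi at 2.20 and Ighg2c at 1.31, and the SEs of the first 4 were larger. Length-adjusted, the call of Mmp3 ended (2.21 ± 0.63), and with limma voom that of Hp (1.91).

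**Figure D3:**
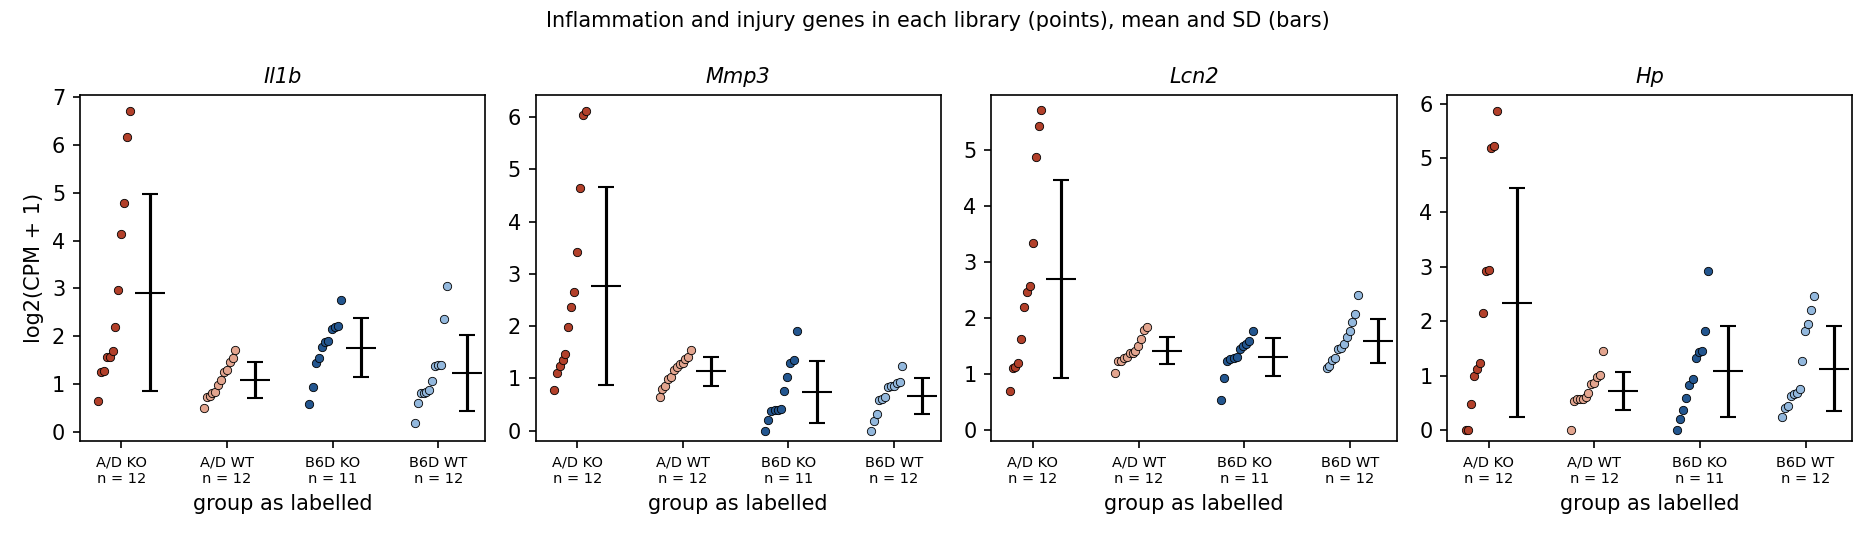
Il1b, Mmp3, Lcn2 and Hp as log2(CPM + 1) (vertical axes) for each library (points, sorted within a group), by group as labelled (horizontal axes); bars are means with SD. For Il1b, the A/D libraries labelled KO reach 104 CPM, while 6 of the 12 lie no higher than the highest A/D WT library.

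The lists fixed beforehand gave the groups of genes that moved in A/D. Of the 17 tested members of the acute-phase and injury list, 13 rose, 0 fell and 4 were not called (14 higher adjusted over the list alone). Lcn2, an antibacterial siderophore-binding protein, rose by 2.88 ± 0.50 (adjusted p = 0.00051). Its gene (chromosome 2, 32384633 to 32388252) lies within 10 Mb of Ptges, a region examined below. Socs3, an inhibitor of cytokine signalling, rose by 1.32 ± 0.19 (adjusted p = 3.1e-05). This list had a median log2 fold change of 1.21 (camera, adjusted p = 1.3e-11; adjusted p = 0.085 with an estimated correlation). Of the 12 neutrophil markers on the list, 4 were tested. All 4 tested neutrophil markers rose (4 adjusted over the list alone), among them Mmp9 by 1.65 ± 0.30 (adjusted p = 8e-04) and Csf3r, the receptor of granulocyte colony-stimulating factor, by 1.54 ± 0.36 (adjusted p = 0.0092). Their median was 1.52 (adjusted p = 0.00037; adjusted p = 0.085 with an estimated correlation). Of the 26 inflammatory cytokines and chemokines on the list, 8 were tested. Of these 8, 4 rose and 4 were not called (5 higher adjusted over the list alone), with Tnf at 1.23 ± 0.30 (adjusted p = 0.011). The cytokine list had an adjusted p of 0.00085 (adjusted p = 0.19 with an estimated correlation). Of 12 plasma cell markers, 7 rose and 5 were not called (8 higher adjusted over the list alone), with Igkc, the kappa light chain, at 0.91 ± 0.23 (adjusted p = 0.014). The plasma cell list had an adjusted p of 3.3e-06 (adjusted p = 0.17 with an estimated correlation). Of 30 cell cycle genes, 7 rose and 23 were not called (24 higher adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase, at 0.45 ± 0.11 (adjusted p = 0.014). The cell cycle list had an adjusted p of 4.4e-11 (adjusted p = 0.19 with an estimated correlation). The antimicrobial lectins Reg3g and Reg3b rose by 2.56 ± 0.51 and 2.55 ± 0.56 (adjusted p = 0.0024 and 0.0058). Their list of 21 defence genes had 4 higher, 1 lower and 16 not called (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.24 for the list). With the smooth muscle score as a covariate the calls of all 9 genes named here ended, with each fold still positive. Lcn2 was then at 1.84 ± 0.60, Socs3 at 0.97 ± 0.23, Tnf at 0.51 ± 0.37, Reg3b at 2.15, Reg3g at 2.14, Mmp9 at 1.36, Igkc at 0.91, Csf3r at 0.60 and Rrm2 at 0.56. The fold of Igkc was not smaller than without the score, and that of Rrm2 was larger. Length-adjusted, the calls of Tnf (0.99), Igkc (0.55), Rrm2 (0.34), Reg3b (1.96) and Csf3r (1.21) ended, and with limma voom those of Lcn2 (1.19), Reg3b (1.55) and Csf3r (0.68). That of Csf3r also ended with the replicate block (1.16) and with only the groups compared (1.54). Of the lists, 7 acute-phase genes, 1 neutrophil marker, 1 cytokine gene and 2 defence genes were then higher length-adjusted (15, 4, 4 and 3 adjusted over the list alone). For plasma cell markers, edgeR called 0 of 12 length-adjusted (9 higher adjusted over the list alone, 9 at an unadjusted p under 0.05), and for cell cycle genes 0 of 30 (7 higher adjusted over the list alone, 19 at an unadjusted p under 0.05). The medians were 0.88 against 1.21 for acute-phase genes, 1.18 against 1.52 for neutrophil markers, 0.84 against 1.10 for cytokines, 0.50 against 0.64 for plasma cell markers and 0.26 against 0.27 for cell cycle genes. All 5 lists were still called length-adjusted, though not with an estimated correlation.

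Smooth muscle genes were lower in A/D libraries labelled KO. Of 15 tested markers, 9 fell and 6 were not called (13 lower adjusted over the list alone). Mylk, the myosin light chain kinase, changed by -0.50 ± 0.10 (adjusted p = 0.0015) and Myh11, smooth muscle myosin, by -0.61 ± 0.13 (adjusted p = 0.0027). The median of this list was -0.40 (adjusted p = 6.3e-13; adjusted p = 0.085 with an estimated correlation). Of 45 xenobiotic metabolism genes, 5 fell and 40 were not called (16 lower adjusted over the list alone), with Ces1d, a carboxylesterase, at -0.62 ± 0.15 (adjusted p = 0.012). The xenobiotic list had an adjusted p of 8.8e-07 (adjusted p = 0.17 with an estimated correlation). Among single genes, St6galnac4, a sialyltransferase (chromosome 2, 32587095 to 32599698), changed by -1.77 ± 0.11 (adjusted p = 4.2e-18), from 70.7 ± 7.62 to 20.5 ± 7.32 CPM. Further large decreases were in Cyp3a44 (-1.43), Col25a1 (-1.30), Unc80 (-1.29) and Lsamp (-1.07). Crat, carnitine acetyltransferase (chromosome 2, 30400471 to 30415813), changed by -0.53 ± 0.06 (adjusted p = 3.5e-07). Length-adjusted, 13 smooth muscle markers fell (14 adjusted over the list alone), and edgeR called 0 of 45 xenobiotic genes (10 lower adjusted over the list alone, 20 at an unadjusted p under 0.05). The medians were then -0.45 against -0.40 and -0.18 in both fits, and both lists were still called, though not with an estimated correlation. The calls of Cyp3a44 (-1.23), Unc80 (-0.88), Lsamp (-0.93) and Ces1d (-0.56) ended length-adjusted. With the smooth muscle score those of Col25a1 (-1.37), Unc80 (-1.11), Lsamp (-0.89), Ces1d (-0.65), Mylk (-0.12) and Myh11 (-0.22) ended. Mylk and Myh11 are among the 15 genes that make up that score, so their folds were bound to shrink.

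Around the targeted pathway, 3 of 20 tested genes of prostaglandin synthesis and receptors rose in A/D, Ptges among them, 2 fell and 15 were not called (4 higher and 2 lower adjusted over the list alone; adjusted p = 0.42 for the list). Ptgs2, cyclooxygenase 2, rose by 1.04 ± 0.24 (adjusted p = 0.0078). Hpgd, which inactivates prostaglandins, and Ptgis, prostacyclin synthase, changed by -0.45 ± 0.09 and -0.67 ± 0.15 (adjusted p = 0.0034 and 0.0061). With the smooth muscle score as a covariate the calls of Ptgs2 (0.54), Hpgd (-0.49) and Ptgis (-0.25) ended. In B6D, 8 of the 20 rose, Ptges among them, 4 fell and 8 were not called (8 and 4 adjusted over the list alone; adjusted p = 0.32 for the list). Over all 14628 tested genes, 7407 were called in B6D, so such counts alone do not mark the pathway. Length-adjusted, Ptges, higher, was the 1 gene of the 20 called in B6D (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.022 for the list; adjusted p = 0.07 with an estimated correlation), against 2 higher and 2 lower in A/D (5 and 3 adjusted over the list alone).

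In all, 797 of 14628 tested genes were called between the A/D groups, 419 higher and 378 lower in libraries labelled KO. At least 2-fold differences were seen for 84 of them (72 higher, 12 lower). With the smooth muscle score as a covariate 27 were called. Length-adjusted, 286 were called (115 higher, 171 lower, or 40.2% higher against 52.6%), of which 219 were among the 797. Leaving out 1 library gave 335 without A/D KO library 12, 415 without KO 9, 487 without KO 4, 506 without WT 7, 507 without WT 9, 1253 without WT 1 and 1328 without KO 5.

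A targeted allele can carry flanking DNA of the donor strain, so calls near Ptges were counted. Of 239 other tested genes within 10 Mb of Ptges, 29 (12.1%) were called in A/D, among them St6galnac4, Crat and Lcn2. Elsewhere 767 of 14388 were called (5.3%; odds ratio 2.45, 95% interval 1.59 to 3.66, Fisher's exact test, two-sided, p = 6.4e-05). Length-adjusted, the odds ratio was 5.44 (3.29 to 8.63, p = 1.6e-09). In B6D, 124 of the 239 were called, an odds ratio of 1.05 (0.808 to 1.37, p = 0.74). Length-adjusted, 2 of them were called in B6D, an odds ratio of 1.51 (0.179 to 5.69, p = 0.39).

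In the B6D line, Mptx1, a mucosal pentraxin (chromosome 1, 174330518 to 174332873), was lower in libraries labelled KO. It changed by -4.65 ± 0.52 (log2 ± SE, n = 11 and 12; adjusted p = 3.4e-08), from 686 ± 704 to 27.4 ± 26.9 CPM (mean ± SD). Spink1, a trypsin inhibitor (chromosome 18, 43728082 to 43737557), changed by -3.49 ± 0.33, from 42.1 ± 17.8 to 3.72 ± 1.27 CPM. Stk32a, a kinase gene on the same chromosome (43207583 to 43318682), changed by -2.27 ± 0.23 (adjusted p = 5.3e-10 for both). The goblet cell peptide Retnlb changed by -2.21 ± 0.31 and the lectin Itln1 by -2.10 ± 0.28 (adjusted p = 2.2e-06 and 1.3e-06). Defa24, a Paneth cell defensin, changed by -4.07 ± 0.96 (adjusted p = 0.00062), the lipase Pnliprp2 by -2.44 ± 0.50 (adjusted p = 0.00013) and the spectrin Spta1 by -2.25 ± 0.45 (adjusted p = 8.9e-05). Ccs, the copper chaperone of superoxide dismutase, changed by -0.99 ± 0.09 (adjusted p = 2.5e-10). Higher genes were Cyp2f2, a cytochrome P450 (3.21 ± 0.49, adjusted p = 3.9e-06), Ptges, Cr2 (2.94), Cd28 (1.75), Irs1 (1.71), Siglecg (1.63), Col8a1 (1.56) and Siglec1 (1.54). Length-adjusted, Mptx1 was at -4.46, Spink1 at -2.45, Stk32a at -2.19, Itln1 at -1.38 and Cyp2f2 at 3.22, all called. The length-adjusted values of Retnlb (-1.10), Defa24 (-3.79), Pnliprp2 (-1.60), Cr2 (3.08), Cd28 (1.36), Irs1 (0.49), Col8a1 (0.98) and Siglec1 (0.99) were not called. Siglecg lost its call with the smooth muscle score as a covariate (1.25), and Defa24 with limma voom. Without the 7 libraries of highest length score, the calls of Defa24, Pnliprp2, Cr2, Cd28, Irs1, Siglecg and Siglec1 ended. Without B6D KO library 8, Defa24 was at -4.74 and Pnliprp2 at -3.23. Mptx1 and the defensins have near-identical relatives, so the share of reads each received is uncertain.

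Extracellular matrix genes rose together in B6D libraries labelled KO, 21 of 25, with 4 not called (22 higher adjusted over the list alone). The collagen Col5a1 was at 0.58 ± 0.11 (adjusted p = 2.8e-05), and the median was 0.44 (adjusted p = 6.1e-06; adjusted p = 0.74 with an estimated correlation). Length-adjusted by edgeR, 0 of the 25 were called (3 higher adjusted over the list alone, 12 at an unadjusted p under 0.05), with a median of 0.31 and the list still called. Of 16 macrophage and monocyte markers, 8 rose, 1 fell and 7 were not called (10 higher and 1 lower adjusted over the list alone). Adgre1, the F4/80 antigen, was at 0.91 ± 0.17 (adjusted p = 4.3e-05; list, adjusted p = 0.029; adjusted p = 0.74 with an estimated correlation). Length-adjusted, 2 macrophage markers rose (12 adjusted over the list alone), and Adgre1 (0.84) was not among them; their median was 0.63 against 0.56 and the list was still called. Of 6 lymphatic endothelium markers, 5 rose and 1 was not called (5 adjusted over the list alone; adjusted p = 0.031; adjusted p = 0.74 with an estimated correlation). Length-adjusted by edgeR, 0 of the 6 were called (1 higher adjusted over the list alone, 1 at an unadjusted p under 0.05), with a median of 0.18 against 0.58 and the list still called. None of these 3 length-adjusted list calls held with an estimated correlation.

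Smooth muscle genes were lower in B6D libraries labelled KO too, with 10 of 15 lower and 5 not called (10 adjusted over the list alone; adjusted p = 0.021; adjusted p = 0.74 with an estimated correlation). The intermediate filament gene Des was at -0.73 ± 0.12 (adjusted p = 1.1e-05) and Tagln at -1.09 ± 0.18 (adjusted p = 9.6e-06). Length-adjusted by edgeR, 0 of the 15 were called (4 lower adjusted over the list alone, 9 at an unadjusted p under 0.05), with a median of -0.29 against -0.42 and the list still called, though not with an estimated correlation. Of 31 fatty acid oxidation genes, 4 rose, 17 fell and 10 were not called (4 and 17 adjusted over the list alone; adjusted p = 0.021; adjusted p = 0.74 with an estimated correlation). Hadh, a dehydrogenase of fatty acid oxidation, was at -0.48 ± 0.08 (adjusted p = 1e-05). Length-adjusted by edgeR, 0 of the 31 were called (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), and the median was -0.07 against -0.28, with the list still called, though not with an estimated correlation. Of 22 unfolded protein response genes, 2 rose, 14 fell and 6 were not called (2 and 14 adjusted over the list alone; adjusted p = 0.034; adjusted p = 0.74 with an estimated correlation). Manf, a secreted stress protein, was at -0.75 ± 0.14 (adjusted p = 5.4e-05). Length-adjusted by edgeR, 0 of the 22 were called (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), the median was -0.03 against -0.27, and the call of the list ended. Of 23 absorptive colonocyte genes, 7 fell and 16 were not called (7 adjusted over the list alone; adjusted p = 0.084 for the list). Over all 14628 tested genes, 3853 fell in B6D. Of the colonocyte list, Car4, a carbonic anhydrase of the cell surface, was at -0.94 ± 0.10 (adjusted p = 5.8e-09). From the bile acid list, Slc51b, an exporter subunit, was at -1.02 ± 0.13 (adjusted p = 4.3e-07). Length-adjusted, 2 of the 23 fell (6 adjusted over the list alone; adjusted p = 1.7e-06 for the list; adjusted p = 0.2 with an estimated correlation), Car4 (-0.58) among them. Slc51b (-0.60) was also still called, Hadh (-0.09) and Manf (-0.05) were not, and without the 7 libraries of highest length score the calls of Hadh, Manf and Tagln ended.

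**Figure D4:**
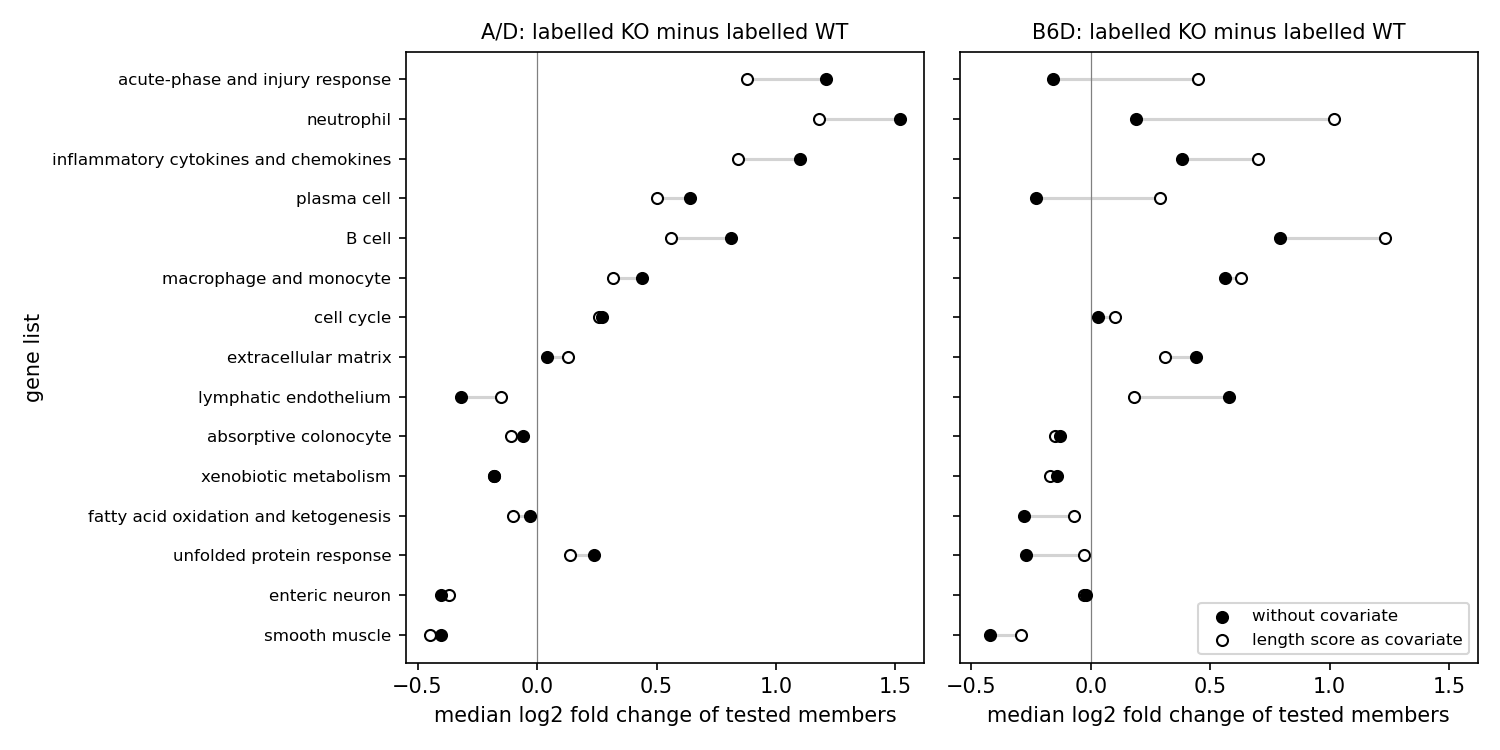
Median log2 fold change of the tested members (horizontal axes) of 15 of the fixed gene lists (vertical axis), libraries labelled KO minus libraries labelled WT, in A/D (left) and B6D (right). Filled circles are fits without a covariate and open circles fits with the length score as covariate; the extracellular matrix median in B6D lies at 0.44 and 0.31, and the acute-phase median in A/D at 1.21 and 0.88.

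In B6D 7407 genes were called, 3554 higher and 3853 lower (48.0% higher). At least 2-fold differences were seen for 283 of them (202 higher, 81 lower). Length-adjusted, 83 were called, 58 higher and 25 lower (69.9% higher), of which 59 were among the 7407. Without the 7 libraries of highest length score, 6 of them B6D WT, 332 were called (107 higher, 225 lower). As 6 of the 12 B6D WT libraries were left out, fewer libraries can account for part of the fall and of the single calls that ended. The libraries were also picked by a score that differed between the B6D groups.

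The difference of the label effects (KO minus WT as labelled), A/D minus B6D, asked for which genes the difference between the labels was not the same in both lines. Spink1 and Mptx1, lower in B6D libraries labelled KO, differed by 4.46 ± 0.47 and 4.38 ± 0.65 (adjusted p = 1.1e-08 and 2.2e-05). The defensin Defa24 differed by 4.06 ± 1.05 (adjusted p = 0.0017). Its relative Defa30 had no count in B6D KO, and with that group at the floor of 3 counts its difference was at least 3.95 (adjusted p = 0.0094). Inflammation genes differed in the same direction, with Hp at 4.15 ± 1.12, Reg3b at 3.96 ± 0.80, Il1b at 3.46 ± 1.01 and Reg3g at 3.43 ± 0.72 (adjusted p = 0.0025, 0.00015, 0.0046 and 0.00024). On the negative side were Cyp2f2 (-3.30 ± 0.59, adjusted p = 3.8e-05), St6galnac4 (-1.91 ± 0.16, adjusted p = 1.7e-12) and Fgf1 (-1.07 ± 0.11, adjusted p = 1e-08). The other negative genes by the naming rule were Plin1 (-2.63), Irs1 (-2.31), Gal3st2c (-2.25), Ncam2 and Unc80 (-2.09 each), and Cyp2w1 and Slc37a2 (-2.06 each). The call of Plin1, a lipid droplet protein, ended without B6D KO library 3 (-1.56, adjusted p = 0.18), and Hp was then at 4.79. That of Slc37a2 ended without A/D WT library 6 or 7, B6D KO library 3, 6 or 9, or B6D WT library 5 or 10, with an adjusted p of up to 0.063. Without B6D KO library 8 Defa24 was at 4.73, and without A/D KO library 9 Il1b was at 2.75. With limma voom Il1b was at 0.70, and its call and those of Hp, Defa30, Defa24 and Plin1 ended. The call of Il1b also ended with the replicate block (2.03), that of Plin1 with DESeq2 and without a filter, and that of Slc37a2 without a filter. Without the 7 libraries of highest length score, the calls of Defa30, Defa24, Hp, Il1b, Plin1, Gal3st2c, Ncam2 and Slc37a2 ended.

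Of 17 acute-phase genes, 14 had a higher effect of the label in A/D and 3 were not called (15 adjusted over the list alone; adjusted p = 0.002; adjusted p = 0.87 with an estimated correlation). Of 22 unfolded protein response genes, 13 were higher, 2 lower and 7 not called (16 higher and 2 lower adjusted over the list alone; adjusted p = 0.0028; adjusted p = 0.87 with an estimated correlation). Duoxa2, a maturation factor of an oxidase, was at 2.18 ± 0.35 (adjusted p = 2.5e-05) and Creld2, a protein of the endoplasmic reticulum, at 1.23 ± 0.18 (adjusted p = 2.2e-05). Extracellular matrix genes differed downward, 14 of 25, with 11 not called (16 adjusted over the list alone; adjusted p = 0.002; adjusted p = 0.87 with an estimated correlation). Postn, a matrix protein, was at -0.62 ± 0.13 (adjusted p = 0.00017). Length-adjusted, edgeR called 0 genes of each of these lists (acute-phase 1 higher adjusted over the list alone, the others 0), with 2, 4 and 2 at an unadjusted p under 0.05. The medians were then 0.32 against 1.66, 0.14 against 0.46 and -0.17 against -0.36, and the lists were still called, though not with an estimated correlation. In all, 7220 genes were called for this difference (3780 higher, 3440 lower), and 1487 without the 7 libraries of highest length score. Length-adjusted, 11 were called (6 higher, 5 lower), with Mptx1 at 4.12, Spink1 at 3.01, St6galnac4 at -2.02 and Fgf1 at -0.87 among them. Il1b was then at -0.14 and Hp at 2.52, and these and the other genes named for this difference were not called. Of the 11, St6galnac4, St6galnac6 and Crat lie within 10 Mb of Ptges on chromosome 2. Fgf1, Arhgap26, Spink1 and AC102496.1 start between 30267249 and 43728082 of chromosome 18. In B6D the cytokine median was 0.38 without the length score and 0.70 with it (camera, adjusted p = 0.46 and 8.5e-05). The neutrophil medians were 0.19 and 1.02 (adjusted p = 0.76 and 0.032), the acute-phase medians -0.16 and 0.45 (adjusted p = 0.46 and 0.11). With an estimated correlation, the cytokine and neutrophil lists were not called (adjusted p = 0.15 and 0.25). With the score, the difference of effects was not called for either list (medians -0.21 and 0.19).

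Calls shared by both lines were fewer than independent lists would give. Of the genes higher in libraries labelled KO, 40 were called in both lines against 101.8 for independent lists (odds ratio 0.321, Fisher's exact test, two-sided, p = 6.5e-15). Of those lower, 32 were called in both against 99.6 (odds ratio 0.252, p = 1.2e-18), while 246 genes were called in opposite directions. Across genes the log2 fold changes of the lines had a Pearson correlation of -0.27, and length-adjusted of 0.23. Length-adjusted, 3 genes were higher in both lines against 0.5, namely Ptges, Trub2 and Marcksl1, the last 2 named after their values were seen. Ptges is the targeted gene, and Trub2 (chromosome 2, 29761224 to 29788502) lies within 10 Mb of it, so this count rests partly on that region.

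Between the lines, libraries labelled WT differed by large folds in single genes. Mptx2, a mucosal pentraxin, was higher in A/D WT than in B6D WT by a log2 fold change of 8.92 ± 0.43 (adjusted p = 2.9e-22; 96.2 ± 53.0 against 0.177 ± 0.173 CPM, n = 12 and 12). Higher in A/D were also Rps3a3 (8.99 ± 0.17, adjusted p = 6.4e-41), Eno1b (6.88), the complement protease gene C1s2 (6.64) and Hmga1b (6.23). In B6D WT no library had a count for Hist1h2al, Ifi44l, Ifi202b or C1rb. Against a floor of 3 counts over the group, these were at least 167-fold, 144-fold, 48.0-fold and 44.4-fold higher in A/D. Lower in A/D was Trim12a, of the tripartite motif family (-9.92 ± 0.28, adjusted p = 1.5e-33; 0.0263 ± 0.0911 against 42.2 ± 11.9 CPM). The MHC class I gene H2-Q2 was at -4.67 ± 0.11 (adjusted p = 9.2e-37). Lower were also Pbp2 (-7.00), Lefty1, a signalling antagonist (-6.10), Pnp2, a purine nucleoside phosphorylase (-5.60), the glutathione transferase Gsta1 (-5.41) and Dmp1 (-5.18). The alpha globin gene Hba-a2 and H60c had no count in A/D WT and were at least 171-fold and 56.3-fold lower. Single libraries moved some folds of groups near 0, with C1s2 at 7.92 without B6D WT library 8 and Pbp2 at -7.78 without A/D WT library 1. The decrease of Trim12a grew without A/D WT library 12, which left that group with no count of it, so no value is given. Many of these genes have near-identical or processed copies elsewhere in the genome, so their counts are uncertain. Of 329 tested pseudogenes 237 were called (72%), against 63.8% of tested protein-coding genes.

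Extracellular matrix genes were higher in A/D WT, 22 of 25, with 3 not called (22 adjusted over the list alone; median 0.69, adjusted p = 1.6e-06; adjusted p = 0.87 with an estimated correlation). The collagens Col5a2 and Col6a1 were at 0.88 ± 0.10 and 0.73 ± 0.09 (adjusted p = 6.9e-10 and 1.2e-09). Of 16 macrophage and monocyte markers, 12 were higher, 1 lower and 3 not called (12 and 1 adjusted over the list alone; adjusted p = 0.0077; adjusted p = 0.87 with an estimated correlation). Among them were the fractalkine receptor Cx3cr1 at 1.24 ± 0.16 and Csf1r at 0.93 ± 0.13 (adjusted p = 1.4e-08 and 9.2e-08). Of 7 dendritic cell markers, 6 were higher and 1 was not called (6 adjusted over the list alone; adjusted p = 0.043; adjusted p = 0.48 with an estimated correlation), with Xcr1 at 2.24 ± 0.33 (adjusted p = 1.1e-07). Of 7 Paneth cell and small intestine genes, 5 were higher, 1 lower and 1 not called (5 and 1 adjusted over the list alone; median 2.76, adjusted p = 0.0089; adjusted p = 0.16 with an estimated correlation). Lyz1, the Paneth cell lysozyme, was at 2.76 ± 0.30, Defa24 at 3.95 ± 0.46 and the intestinal phosphatase Alpi at 1.02 ± 0.11 (adjusted p = 1.1e-10, 1.5e-09 and 2.5e-11). Of 11 genes of antigen presentation by MHC class II, 7 were higher, 1 lower and 3 not called (7 and 1 adjusted over the list alone; adjusted p = 0.13 for the list). Length-adjusted, 7 of the 11 were higher (9 adjusted over the list alone), with a median of 1.42 against 1.07, and the list was called (adjusted p = 0.0014; adjusted p = 0.66 with an estimated correlation). H2-Aa was at 1.41 ± 0.27 and the class II transactivator Ciita at 2.12 ± 0.30 (adjusted p = 2.5e-05 and 1.2e-07). Cbr1, a carbonyl reductase that also acts on prostaglandins, was at -1.41 ± 0.10 (adjusted p = 1.6e-17). Ptges was at 0.22 ± 0.12 (adjusted p = 0.12), but was called length-adjusted (0.56) and without the 7 libraries of highest length score (0.44).

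In all, 9266 genes were called between libraries labelled WT (4698 higher, 4568 lower in A/D), 1323 of them at least 2-fold (843 higher, 480 lower). Length-adjusted 3415 were called (1750 higher, 1665 lower), and 5194 without the 7 libraries. The length score differed by -0.68 and the smooth muscle score by -0.29 between these groups (permutation tests, two-sided, p = 4e-05 and 3e-05, BH-adjusted 0.00011 for both).

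Between the lines' libraries labelled KO, genes of intestinal defence, plasma cells and antigen presentation were higher in A/D. Itln1, a lectin of goblet and Paneth cells, was at 4641 ± 1220 CPM (n = 12) in A/D KO and 70.9 ± 34.6 (n = 11) in B6D KO, a log2 fold change of 6.04 ± 0.33 (adjusted p = 5.1e-20). Wfdc2, a secreted protease inhibitor of epithelia, went the other way, with -3.75 ± 0.23 (adjusted p = 1.2e-18). Of 21 defence genes, 13 were higher, 4 lower and 4 not called (13 and 4 adjusted over the list alone; adjusted p = 0.002; adjusted p = 0.086 with an estimated correlation). Of 17 acute-phase genes, 15 were higher and 2 not called (15 adjusted over the list alone; median 1.51, adjusted p = 2.7e-06; adjusted p = 0.21 with an estimated correlation). The inducible nitric oxide synthase Nos2 was at 2.97 ± 0.37 and the serum amyloid gene Saa3 at 2.60 ± 0.32 (adjusted p = 1.5e-08 and 1.1e-08). Of 12 plasma cell markers, 8 were higher and 4 not called (9 adjusted over the list alone; adjusted p = 1.1e-05; adjusted p = 0.21 with an estimated correlation). The B cell coactivator Pou2af1 was at 1.89 ± 0.21 and the J chain gene Jchain at 1.32 ± 0.18 (adjusted p = 1.7e-10 and 1e-07). Of 11 MHC class II genes, 10 were higher and 1 not called (10 adjusted over the list alone; median 1.63, adjusted p = 2.1e-05; adjusted p = 0.31 with an estimated correlation). H2-Aa was at 1.79 ± 0.28 and the invariant chain Cd74 at 1.63 ± 0.27 (adjusted p = 2.6e-06 and 6.2e-06). Of 25 genes of the interferon gamma response and MHC class I, 16 were higher, 1 lower and 8 not called (16 and 1 adjusted over the list alone; adjusted p = 0.00017; adjusted p = 0.67 with an estimated correlation), with Gbp4 at 1.99 ± 0.22 (adjusted p = 2.9e-10). Of 7 Paneth cell and small intestine genes, 5 were higher, 1 lower and 1 not called (5 and 1 adjusted over the list alone; median 2.35, also with Defa30 at its bound; adjusted p = 1.1e-05). Lyz1 was at 2.35 ± 0.30 and Alpi at 0.82 ± 0.11 (adjusted p = 1.7e-08 and 2.4e-08). Of the list calls in the 5 comparisons, without a covariate, this was the 1 that held with an estimated correlation (adjusted p = 0.0023).

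Mptx2 was higher in A/D KO than in B6D KO by 11.23 ± 0.56 (adjusted p = 1e-21). Higher in A/D KO were also Rps3a3 (9.63), Ifi44l (8.21), Defa24 (8.02), Ang5, an angiogenin-family gene (7.17), and Hmga1b (6.54). Hist1h2al, Defa30 and Ifi202b had no count in B6D KO and were at least 167-fold, 166-fold and 77.8-fold higher. Lower were Trim12a (-8.58 ± 0.27, adjusted p = 1.1e-31), Lefty1 (-7.23), Azgp1, a secreted glycoprotein (-5.85), Dmp1 (-5.52), the interferon-inducible Mndal (-5.30) and H2-Q2 (-4.06). Pbp2, H60c and Hba-a2 had no count in A/D KO and were at least 214-fold, 88.4-fold and 76.2-fold lower. Mptx2 was at 11.98 without B6D KO library 1, Ifi44l at 8.97 without B6D KO library 4, Defa24 at 8.69 without B6D KO library 8 and Lefty1 at -8.01 without A/D KO library 7. Gsta1 was at -4.56 ± 0.31 (adjusted p = 1.2e-17), Cbr1 at -0.99 ± 0.10 (adjusted p = 7.8e-12) and Ptger4, a prostaglandin E2 receptor, at -0.68 ± 0.10 (adjusted p = 4.5e-07). Ptges was at 0.18 ± 0.10 (adjusted p = 0.21). Of 15 smooth muscle markers, 9 were lower and 6 not called (11 adjusted over the list alone; adjusted p = 0.00025; adjusted p = 0.54 with an estimated correlation), with Casq2 at -1.32 ± 0.18 (adjusted p = 3.4e-08). The smooth muscle score differed by -0.42 and the length score by 0.21 (permutation tests, two-sided, p = 0.0018 and 0.044, BH-adjusted 0.0024 and 0.044). In all, 4115 genes were called (2176 higher, 1939 lower in A/D), 877 of them at least 2-fold (567 higher, 310 lower).

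Line differences called under both labels were more than independent lists would give, while for 7220 genes the difference of the label effects, which is also that of the line differences, was called. Of the genes higher in A/D, 1181 were called in both comparisons against 698.9 for independent lists (odds ratio 3.02, Fisher's exact test, two-sided, p = 1.5e-119). Of those lower, 1012 were called in both against 605.5 (odds ratio 2.80, p = 7e-95), with 498 called in opposite directions. The Pearson correlation of log2 fold changes across genes was 0.75, and length-adjusted 0.90.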

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

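Tests chosen after the result was seen were those of single mislabelled libraries, of exchanged labels or an altered allele, of both causes weighed for the inflammation genes, and all fits with the length score or without the 7 libraries of highest length score.

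The effect of the KO label differed between A/D and B6D, by the test of the difference itself, for 7220 genes, but for 11 with the length score and 1487 without the 7 libraries of highest length score. In log2 fold change of A/D minus B6D, the named genes were Spink1 (4.46), Mptx1 (4.38), Hp (4.15), Defa24 (4.06), Reg3b (3.96), Il1b (3.46), Reg3g (3.43), Cyp2f2 (-3.30), Plin1 (-2.63), Irs1 (-2.31), Gal3st2c (-2.25), Ncam2 (-2.09), Unc80 (-2.09), Cyp2w1 (-2.06), Slc37a2 (-2.06), St6galnac4 (-1.91) and Fgf1 (-1.07). Defa30 had no count in B6D KO, so its fitted value of 5.02 is not a measured difference, and with that group at the floor of 3 counts the difference was at least 3.95. Plin1 was at -1.56 and not called without B6D KO library 3, and 7 single libraries each ended the call of Slc37a2 when left out. With the length score Spink1 (3.01), Mptx1 (4.12), St6galnac4 (-2.02) and Fgf1 (-0.87) were still called and the other 14 were not, with Il1b turning to -0.14. St6galnac4 lies within 10 Mb of Ptges, and Spink1 and Fgf1 both lie on chromosome 18. Without the 7 libraries the calls of Defa30, Defa24, Hp, Il1b, Plin1, Gal3st2c, Ncam2 and Slc37a2 ended.

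Of 100 splits of the libraries into groups of these sizes, 1, the real one, gave as many genes as the difference of effects. The highest other split gave 3205. This argues against a random grouping as the source of the whole count, but 100 splits cannot show a share under 1 of 100. In the other comparisons too, only the real split gave as many genes. These were 797 in A/D (1 of 100, highest other 71), 7407 in B6D (1 of 100, highest other 5940), 9266 between lines labelled WT (1 of 100, highest other 5430) and 4115 between lines labelled KO (1 of 100, highest other 28). Other splits with many genes, such as those of 5940 and 5430, point to a structure of the libraries beyond the groups.

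Ptges was higher in libraries labelled KO in both lines. Single mislabelled libraries are argued against, since the lowest library labelled KO lay 2.10 times as high as the highest labelled WT in A/D, and 2.98 times in B6D. A rise of the whole neighbourhood is argued against as well, since over the 8 other tested genes within 100 kb the smaller of a gene's log2 fold changes in A/D and B6D was at most -0.04 (Usp20). Labels exchanged in both lines and reads from an altered allele that still yields RNA cannot be told apart, because either could give the same fold in both lines, and the folds differed by -0.04 ± 0.16. The labels do not say which part of the gene was removed, and counts per gene keep no exons.

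A large share of all tested genes, 7407 of 14628, was called in B6D. A difference in smooth muscle share as the whole cause is argued against, since 6005 genes were called with that score as a covariate. A trend with transcript length between libraries is consistent with the values: within each of the 4 groups the first component of the libraries had loadings correlated with transcript length across genes (lowest absolute Spearman correlation 0.42), and length-adjusted 83 genes were called. The length score itself differed between B6D KO and WT, so for the genes no longer called, an effect of the genotype stays open, as untested apart from the label.

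Inflammation and injury genes were higher in A/D libraries labelled KO, with a median log2 fold change of 1.36 (median SE 0.33) over the 17 called members of the acute-phase and cytokine lists. Lcn2, among the 17, lies within 10 Mb of Ptges. The length trend as the whole cause is argued against, since the length-adjusted median was 1.08 (median SE 0.35), though 8 of the 17 were still called. With the smooth muscle score as covariate the median was 0.97 (median SE 0.42), and edgeR called 0 of 17 (12 at an unadjusted p under 0.05). Errors were larger in that fit, and folds were smaller except for Duoxa2 (1.02 against 0.90). Over all tested genes, 27 were called in A/D in that fit, against 797 without the score. A lower share of muscle alone would raise markers of every other cell type alike. Over 6 lists of other cell types the highest median in A/D was 0.16 (tuft cell, median SE 0.14). The 17 genes were picked as called higher, which raises their median. Over all tested members the medians were 1.21 for acute-phase genes and 1.10 for cytokines. For these genes, the list medians argue only against a plain shift in the share of muscle as the whole cause. The comparison was set after the median of 0.97 was seen, and the fit with the score alone does not decide the question. A rise of inflammation along with the loss of muscle stays open, and an effect of the genotype stays open too, as untested, since Ptges goes against the label.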

How the results depend on the processing

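Fits with the length score and without the 7 libraries of highest length score were tests chosen after the data were seen. Unless a cause is named, the cause was not tested.

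For A/D, 797 genes became 489 with no filter (more genes tested), 27 with the smooth muscle score (19 higher, 8 lower), 1844 with limma voom and 286 with the length score. For B6D, 7407 became 83 with the length score and 332 without the 7 libraries. For the difference of effects, 7220 became 11 and 1487 in these fits, and for the lines labelled WT 9266 became 3415 and 5194. For the lines labelled KO, the 9 other settings and the fit without the 7 libraries gave 2953 to 4884 genes against 4115, all within 1.5 times. Calls shared by the KO comparisons of both lines, 72, became 11 at a threshold of 0.01 and 180 at 0.1, by construction, and 3 with the length score. The excess of A/D calls near Ptges, and the odds ratio in B6D, kept direction and side of the threshold with windows of 5 and 20 Mb and with the length score. Leaving out 1 library gave 335 to 1328 genes in A/D, 6752 to 8003 in B6D, 6767 to 7744 for the difference, 8889 to 9615 for the lines labelled WT and 3741 to 4356 for those labelled KO. In A/D the count moved over 1.5 times without KO 12 (335), KO 9 (415), KO 4 (487), WT 7 (506), WT 9 (507), WT 1 (1253) and KO 5 (1328).

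With the replicate number as a block, 454 genes were called in A/D, and the other counts stayed within 1.5 times. The pairing check found no pairs: mean correlations of same-numbered libraries around their group means ran from -0.10 to 0.06, and at most 3 of 11 libraries correlated best with their own number.

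For single genes, 152 results were refitted. Direction and side of the threshold were kept in 1351 refits, the call was lost in 119, 46 of them with the length score and 30 with the smooth muscle score, and gained in 8. The sign turned once, for Il1b in the difference of effects with the length score (-0.14 against 3.46; adjusted p 0.00039 to 1 over its settings). Of 56 list calls, 1 held with an estimated correlation, 51 with the length score and 40 with the smooth muscle score. With the latter the direction turned for smooth muscle genes, which make up that score, in A/D (adjusted p = 0.84, over all settings 9.8e-21 to 0.84) and between lines labelled KO (adjusted p = 0.94, 1e-04 to 0.94), and for fibroblast genes in A/D (adjusted p = 0.58, 0.011 to 0.58). Depth limits genes with few counts, since 3 counts over a group came to 0.0363 to 0.0415 CPM.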

Other observations

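The test of calls close together, the fits with the length score and the tests of mast cell genes by library were chosen after the values were seen.

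Mast cell genes varied widely between libraries of 1 group. Mcpt1, a mast cell protease of the mucosa, ran from 20.8 to 666 CPM in A/D KO (median 99.6), from 5.32 to 834 in A/D WT (13.2), from 2.54 to 345 in B6D KO (111) and from 0.379 to 199 in B6D WT (16.7). In B6D, Cpa3, a carboxypeptidase of mast cells, was higher in libraries labelled KO by a log2 fold change of 2.25 ± 0.75 (adjusted p = 0.012, edgeR), and by 2.92 without B6D WT library 5. Its call ended without the 7 libraries of highest length score. Mcpt1 was at 1.64 ± 0.81 (adjusted p = 0.087) and Mcpt2 at 1.78 ± 0.81 (adjusted p = 0.065). Mcpt1 was called without A/D WT library 1 or B6D WT library 5 (adjusted p = 0.031 and 0.028), and Mcpt2 without these or B6D KO library 3 or 7 (adjusted p = 0.018, 0.023, 0.047 and 0.049). In A/D, 0 of 7 mast cell genes were called (0 adjusted over the list alone), with a median of 0.55. By camera the list was called there (adjusted p = 0.0023; adjusted p = 0.33 with an estimated correlation). Its length-adjusted median in A/D was 0.05 (adjusted p = 0.031; adjusted p = 0.43 with an estimated correlation). Of 7 mast cell genes in B6D, 1 was higher and 6 were not called (1 adjusted over the list alone; adjusted p = 0.29 for the list). Length-adjusted, 6 were higher (6 adjusted over the list alone), with a median of 4.91 against 1.72 without the score (adjusted p = 4.1e-12; adjusted p = 0.042 with an estimated correlation). The length score itself differed between B6D KO (-0.21 ± 0.15, mean ± SD) and B6D WT (0.44 ± 0.43). The larger adjusted fold therefore depends on how the fit extends the trend between these groups, and is not an observed difference.

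Immune receptor segments, constant genes included, were called in A/D in 1 direction: of 166 tested, 25 were called, each higher in libraries labelled KO, and length-adjusted 8 were called. In the A/D line, 5 of 16 macrophage and monocyte markers were higher and 11 not called (11 higher adjusted over the list alone; adjusted p = 3.9e-05; adjusted p = 0.27 with an estimated correlation). Length-adjusted by edgeR, 0 of the 16 were called (4 higher adjusted over the list alone, 9 at an unadjusted p under 0.05), with a median of 0.32 against 0.44 and the list still called, though not with an estimated correlation. Enteric neuron genes were lower, 2 of 16, with 14 not called (9 lower adjusted over the list alone; adjusted p = 8.8e-07; adjusted p = 0.17 with an estimated correlation), and length-adjusted 1 was lower (7 adjusted over the list alone), with a median of -0.37 against -0.40.

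Spink1, Stk32a, Fgf1, Arhgap26 and Lars were all called in B6D with the length score and lie between 38 and 44 Mb of chromosome 18, where 24 genes were tested. This raised the hypothesis that calls in B6D may gather in a region. Windows of 10 Mb from each called gene were scanned over all chromosomes, with 10000 permutations of the calls over the tested genes. Relative to the tested genes of a window, the calls were densest in the window of these 5, which held 5 of the 83 calls among 33 tested genes against 0.19 at an even spread (hypergeometric p = 1.1e-06). As small a p in any window was reached with a permutation p = 7e-04, which argues against an even spread of the calls. By the number of calls alone, no window held more than 5, reached with a permutation p = 0.17, and this count favours regions with many genes. The measure relative to the tested genes was settled on after a first result of the scan was seen. Its permutation p does not allow for that choice. DNA that differs between the B6D groups in this region, and neighbours regulated together, were not tested and stay open. In A/D the densest window by the same measure lay on chromosome 2 from 25352276 to 32787602 and held 20 of 286 calls among 171 tested genes, Ptges among them (permutation p = 1e-04, the smallest these permutations can give).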
